A study of Mus musculus with 24 samples.

How the data were processed

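RNA was measured in mpkCCD cells treated on the basolateral side with dDAVP or vehicle for 3, 6, 12 or 24 h, with 3 libraries for each of the 8 groups. Per the labels, total RNA was extracted with Trizol and a Direct-zol kit, cDNA was made with SMART-Seq HT, and libraries were made with Nextera reagents. The estimated counts per Ensembl gene were made by the authors from the reads, without normalization, and hold fractions for many genes. The TPM table was also made by the authors and deposited in the same layout, each column scaled to a fixed total. Salmon 0.14.10 and GRCm38.p6 are named in the submitters' processing notes; the aligner settings and the way transcripts were summed to genes are not given in the sources used here. All 24 columns of each table were matched to their labels, and 0 were left out.

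Estimated counts were rounded to whole numbers and analysed with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Library sizes were scaled by TMM (factors 0.814 to 1.326), and 29743 of 54432 genes were kept by filterByExpr over the 8 groups. A model with 1 mean per group was fitted to all 24 libraries, genes were tested with the quasi-likelihood F test, and p was adjusted by the Benjamini-Hochberg method (BH) over the genes tested, with 0.05 as the threshold. This test and adjustment stand behind every adjusted p of a gene, and list tests are named as such. Comparisons were dDAVP against vehicle at each time, the mean of the 4 effects, the dependence of the effect on time (F test of 3 contrasts), the effect at 24 h minus that at 3 h, and vehicle at 24 h against 3 h. These comparisons, the alternatives to them, the gene lists and the rule for naming genes were written before the data were examined. The counts carry no correction for transcript length, so they compare libraries within a gene and not genes with each other.

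Fixed lists, 48 in all, were tested with camera from limma, with the correlation between genes estimated for each list and p adjusted over the lists of a comparison. Members called over all genes and members with p adjusted over the list alone were counted beside it. Alternatives for lists were a preset correlation of 0.01 and fry. Camera asks whether a list stands apart from the other genes, and fry whether its members change at all. Their counts therefore answer different questions. Receptor shares were compared by exact or sampled permutation (100000 permutations). Gene names came from GENCODE M21 (Ensembl 96) by identifier: 54346 identifiers had a name and 86 had none. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

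Genes were named by rule. For each time these were the 10 largest rises and the 10 largest falls among genes past the threshold with at least 5 CPM in the higher group, a gene symbol that is not only a clone or predicted-gene name, and all dDAVP libraries beyond all vehicle libraries. A fixed set of 15 genes was always named, as were up to 4 members with the smallest p of each list described, and the 10 genes with the smallest p in the comparisons of time dependence, mean effect and vehicle. Values of some genes that meet the rule are not reported here.

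Alternatives chosen beforehand were median-of-ratios size factors (RLE), DESeq2 1.42.0, no filter, a filter of at least 5 CPM in a group (13123 genes), a replicate block, limma on log2 TPM with 1 or 0.1 added, only the libraries compared, a threshold of 0.01, and leaving out each library in turn. The filter used unscaled library totals and was followed by a new fit and TMM scaling, whereas CPM elsewhere used TMM library sizes. After seeing the data, the log2 share of counts in 1459 olfactory and vomeronasal receptor genes (1135 and 324) was added to the model as a covariate, alone and with the 5 CPM filter; fits without the 2 libraries of highest share, lists without Aqp2, and list tests on the mean effect and in vehicle were added too. These 1459 genes were taken as silent in this epithelium, and 99.73% of them had a count in at least 1 library. The log2 shares of the olfactory and vomeronasal genes had a correlation of 0.9995 across libraries.

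Depth was 17.25 to 27.64 M estimated counts per library, with 36676 to 46296 genes holding a count. The common dispersion was 0.0366 (biological coefficient of variation 0.191), and 0.00636 (0.0798) with the covariate. Replicates differed by a chi-square of 3.541 to 61.14 per gene between pairs, so no library duplicated another.

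The fit was tested on simulated data with known changes in 200 genes (67 of 1.5-fold, 67 of 2-fold and 66 of 4-fold) at each time. Counts were drawn independently for each gene, without the variation in receptor share that genes of the real libraries have in common. The rates of recovery and of false calls therefore need not hold for the real libraries. The share of changed genes recovered at 1.5-, 2- and 4-fold was 41.8%, 91% and 100% at 3 h, 46.3%, 91% and 95.5% at 6 h, 61.2%, 91% and 100% at 12 h, and 40.3%, 88.1% and 100% at 24 h, with 2.5%, 3.1%, 7.7% and 1.9% of calls false. With the covariate it was 26.9%, 85.1% and 100% at 3 h, 14.9%, 73.1% and 95.5% at 6 h, 55.2%, 91% and 100% at 12 h, and 38.8%, 88.1% and 100% at 24 h, with 2.1%, 3.2%, 7.9% and 2.6% false calls.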

Results

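Gene expression was profiled by RNA sequencing in mpkCCD cells, an epithelial line from the cortical collecting duct of the mouse kidney, over a time course of exposure to dDAVP. This synthetic vasopressin analogue activates the V2 receptor. Cells had spent 6 days on permeable filters and 24 h in minimal medium before dDAVP or vehicle was applied to the basolateral side for 3, 6, 12 or 24 h. The 8 groups of treatment and time held 3 libraries each, 24 in all. Total estimated counts (M, mega) in vehicle replicates 1, 2 and 3 were 18.35, 18.86 and 21.12 M at 3 h, 17.25, 18.24 and 20.33 M at 6 h, 20.27, 21.56 and 17.48 M at 12 h, and 22.75, 24.05 and 21.82 M at 24 h. In dDAVP they were 20.3, 24.63 and 20.07 M at 3 h, 27.64, 22.16 and 25.27 M at 6 h, 22.97, 21.92 and 21.02 M at 12 h, and 22.55, 18.89 and 23.12 M at 24 h. The labels do not say that replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical. Of 54432 genes in the tables, 29743 had enough counts to be tested.

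Olfactory and vomeronasal receptor genes, whose products are known from sensory neurons of the nose, held between 0.135% and 0.901% of the counts of a library. Their share averaged 0.629% ± 0.257 (SD, n = 3) in vehicle and 0.374% ± 0.121 in dDAVP at 3 h, 0.526% ± 0.0728 and 0.196% ± 0.0727 at 6 h, 0.477% ± 0.285 and 0.335% ± 0.0524 at 12 h, and 0.226% ± 0.0655 and 0.201% ± 0.0443 at 24 h. Within single times no difference could pass, since 0.1 is the smallest exact p that 3 against 3 libraries can give. The exact permutation p, counting both directions, was 0.2, 0.1, 0.5 and 0.7 (adjusted 0.333, 0.25, 0.625 and 0.7 over 5 comparisons). The fifth comparison, vehicle at 24 h against vehicle at 3 h, gave 0.1 (adjusted 0.25). Over all times, with labels permuted within times, the share was 0.188 percentage points lower in dDAVP (0.276% against 0.464%, permutation p = 0.0064). Across the 24 libraries the log2 share went with the number of genes that had a count (Pearson r = 0.965, Spearman rho = 0.969, each permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted 2e-05 over 2 relations). It went against the total count (r = -0.624, permutation p = 0.0011, adjusted 0.0011; rho = -0.659, permutation p = 0.00051). Without the 2 libraries farthest from the median share, r was 0.955 and -0.606. The total count is the divisor of the share, and receptor genes are among the genes with a count, so each relation is partly built in. For these relations values were permuted over all 24 libraries and not within groups.

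**Figure D1:**
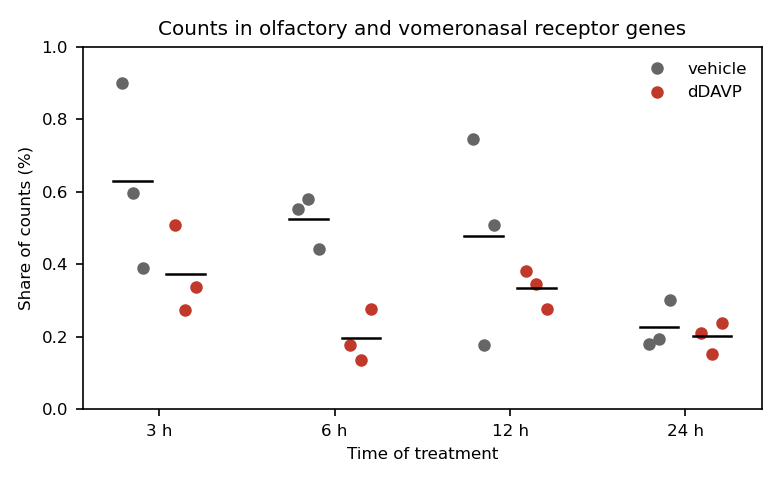
Share of counts in olfactory and vomeronasal receptor genes (y axis, percent of the library's counts) by time of treatment (x axis), with 1 point per library and a line at the mean of 3. The dDAVP libraries at 6 h average 0.196% and the vehicle libraries at 3 h average 0.629%.

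At 3 h, dDAVP raised Aqp2, the vasopressin-regulated water channel of the collecting duct (ENSMUSG00000023013, GRCm38 chromosome 15, 99579055 to 99584547), from 5.74 ± 0.722 to 119 ± 8.51 CPM (counts per M counts, mean ± SD, n = 3; log2 fold change 4.38 ± 0.165 SE, adjusted p = 3.1e-15). Ramp3, an accessory protein of calcitonin-family receptors (chromosome 11, 6658521 to 6677475), rose from 0.478 ± 0.0953 to 7.42 ± 0.599 CPM (log2 3.95 ± 0.312, adjusted p = 1.99e-08). The orphan nuclear receptor Nr4a2 (chromosome 2, 57106830 to 57124003) rose from 6.58 ± 0.389 to 29.3 ± 3.5 CPM. The cAMP phosphodiesterase Pde4b (chromosome 4, 102087543 to 102607259) rose from 3.63 ± 0.32 to 14.3 ± 0.922 CPM. Among lower genes, the Ras-like gene Rasl11a fell from 12.4 ± 2.63 to 3.61 ± 0.805 CPM (log2 -1.78 ± 0.203), and the prostaglandin E2 receptor Ptger1 from 19.6 ± 2.78 to 6.71 ± 1.2 CPM (-1.55 ± 0.251). Scnn1g, the gamma subunit of the epithelial sodium channel, fell from 14.7 ± 3.98 to 7.55 ± 1.81 CPM (-0.96 ± 0.191, adjusted p = 0.0109).

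The other genes with the largest rises at 3 h were the glycosyltransferase B3gnt7 (log2 3.00), the mitochondrial arginase Arg2 (2.13), the actin-binding Cotl1 (1.91), the ceramide kinase Cerk (1.65), the cytochrome P450 Cyp1b1 (1.64) and the carbonyl reductase Cbr3 (1.62). The fourth gene named on the lower side was Veph1 (-0.58). In all, 144 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 139 higher and 5 lower, of which 44 and 3 changed at least 2-fold.

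Of 38 tested genes for cAMP turnover and protein kinase A, 3 rose and 0 fell at 3 h (12 and 0 adjusted over the list alone): Pde4b, the anchoring protein Akap12 (log2 1.47) and the CREB coactivator Crtc1 (0.54). Pde7a had log2 0.51 with adjusted p = 0.0756. The list stood above other genes in the camera test (adjusted p = 0.00343 over 48 lists; 0.00642 with the receptor share in the model; 0.431 with median-of-ratios scaling). Of 27 CREB-associated and immediate early genes, 4 rose and 0 fell (11 and 1 adjusted over the list alone), namely Nr4a2, the kinase Sik1 (1.17), the cAMP-inducible repressor gene Crem (1.25) and the AP-1 gene Fosl2 (0.58). That list gave camera adjusted p = 0.136, 0.04 with the receptor share in the model, 0.0942 with that share and the 5 CPM filter, and 0.431 with median-of-ratios scaling. Among 20 principal cell markers, Aqp2 rose, Scnn1g fell and no other member passed (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.21, with median -0.05 and mean 0.16). Nr4a1 (0.65), Elf3 (0.53), Per1 (0.39), Fos (0.02), Sgk1 (0.18), Creb1 (0.17), Cebpb (1.92, SE 0.606), Aqp3 (-0.17), Aqp4 (-0.06), Avpr2 (-0.35), Scnn1a (-0.05) and Scnn1b (-0.46) did not pass at 3 h.

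With the log2 receptor share as a covariate, a model chosen after seeing the data, 215 genes were called at 3 h, 143 of them shared with the 144. Elf3 (0.36, adjusted p = 0.00684) and Avpr2, the V2 receptor itself (-0.52, adjusted p = 0.00059), passed in that model. The median log2 fold change was -0.14 over all tested genes and 0.18 over genes of at least 5 CPM, and 0.05 and 0.04 with the covariate. Small changes, and the counts of list members adjusted over the list alone, are relative to these shifts. Leaving out vehicle replicate 1 or 2 or dDAVP replicate 2 or 3 gave 72, 87, 71 and 63 genes. Scnn1g lost its call without vehicle replicate 2 (adjusted p = 0.216) or dDAVP replicate 2 (0.246). Veph1 lost it without vehicle replicate 2 (0.132) or dDAVP replicate 1 or 2 (0.0628 and 0.0685). Crtc1 did without vehicle replicate 1 or dDAVP replicate 2 or 3 (0.0559, 0.055 and 0.192), and Fosl2 without any of 5 libraries, all but dDAVP replicate 1 (0.085 to 0.575).

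At 6 h, Aqp2 stood at 199 ± 28.3 CPM in dDAVP and 5.07 ± 0.966 in vehicle (log2 5.29 ± 0.172, adjusted p = 8.64e-17). Ramp3 was higher by log2 3.26 ± 0.296, the transcriptional coactivator Cited1 by 2.76 ± 0.312, the membrane-curving protein gene Baiap2l2 by 2.46 ± 0.184, and B3gnt7 by 2.34 ± 0.162. The serine protease gene Tmprss4 was higher by 2.07 ± 0.197 and Pde4b by 1.97 ± 0.164. Nr4a1, an immediate early nuclear receptor, rose from 20.7 ± 2.48 to 58.3 ± 3.63 CPM (1.49 ± 0.158, adjusted p = 1.75e-06). Ptger1 fell from 20.4 ± 4.6 to 6.79 ± 1.27 CPM (-1.58 ± 0.251, adjusted p = 0.000655) and Scnn1g from 13.2 ± 0.861 to 8.08 ± 1.22 CPM (-0.71, adjusted p = 0.0183). Each of these calls held with the receptor share in the model. There Ramp3 was at 2.76, Baiap2l2 at 2.16, B3gnt7 at 2.04, Ptger1 at -1.62 and Scnn1g at -0.99. Cotl1 (2.09) and Arg2 (1.99) also rose in both models.

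Over all tested genes, 11320 were called at 6 h, 6203 higher and 5117 lower, with 162 and 4230 changed at least 2-fold. The vehicle libraries at 6 h held more receptor-gene counts than the dDAVP libraries (0.526% against 0.196%), and the median log2 fold change was -0.39 over all tested genes and 0.32 over genes of at least 5 CPM. Of the higher genes 96.2% were protein coding and 98.6% reached 5 CPM in a group; of the lower genes 47.6% and 27.8%. In all, 7536 of the 11320 were genes of at least 5 CPM. A new fit to the 13123 genes past the 5 CPM filter, with its own scaling, called 2500 (2125 shared with the 11320), and more of these were lower than higher (722 higher, 1778 lower). With the receptor share in the model 100 were called (83 higher, 17 lower; 85 shared). The genes with the largest falls other than Ptger1 were Lrrc7 (-1.71), Daam2 (-1.55), the calcium channel gene Cacna1e (-1.46), Cryzl2 (-1.45) and the neurotrophin receptor gene Ntrk2 (-1.42). With them were the sensory receptor genes Vmn2r101 (-1.51), Olfr398 (-1.51), Olfr56 (-1.48) and Olfr1330 (-1.43). With the covariate these lay between -0.09 (Ntrk2) and -0.52 (Cryzl2 and Vmn2r101) and none passed. The sensory receptor genes are counted in the receptor share itself, so their smaller effects with the covariate are no independent result. Receptor genes share sequence with near copies, so their single values are uncertain.

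The CREB-associated and immediate early list had 5 members higher and 0 lower at 6 h with the receptor share in the model (12 and 1 adjusted over the list alone; camera adjusted p = 0.0118), led by Nr4a1, Nr4a2 (1.07), Nr4a3 (2.20) and Sik1 (0.71). Nr4a3 was at 1.265 without the covariate (adjusted p = 0.0229). Without the covariate 20 rose and 0 fell (22 and 0 adjusted over the list alone) and camera gave 0.162. The cAMP turnover and protein kinase A list had 2 members higher and 0 lower with the covariate, Pde4b (2.06) and Akap12 (0.98; 7 and 0 adjusted over the list alone; camera adjusted p = 0.0148). Without it 15 rose and 6 fell (15 and 7 adjusted over the list alone) and camera gave 0.0774. Without the covariate, 0 of 48 lists passed camera, against 8 at an unadjusted p under 0.05 and 44 by fry. Over all tested genes 6203 were called higher and 5117 lower without it, so counts of called members alone do not set a list apart. Crem (1.04), Fos (0.92), Per1 (0.60), Elf3 (0.55) and Cebpb (2.98, SE 0.659) passed at 6 h without the covariate and not with it (adjusted p = 0.125, 0.214, 0.837, 0.761 and 0.196). There Crem was at 0.579, Fos at 0.537, Per1 at 0.308, Elf3 at 0.195, and Cebpb, little changed, at 2.77 with a larger SE of 0.77. Sgk1 (0.18), Creb1 (0.23), Avpr2 (0.25), Aqp3 (-0.12), Aqp4 (-0.42), Scnn1a (0.16) and Scnn1b (-0.59) passed in neither. With the covariate Creb1, Avpr2 and Scnn1a were at -0.149, -0.107 and -0.35.

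The count at 6 h was 252 without vehicle replicate 1, 165 without vehicle replicate 2, 4697 without vehicle replicate 3, 185 without dDAVP replicate 1 and 84 without dDAVP replicate 2. Scnn1g missed the threshold without vehicle replicate 1 or 2 or dDAVP replicate 1 or 2 (adjusted p 0.06, 0.0775, 0.0834 and 0.0859). Without vehicle replicate 1 or 2 or dDAVP replicate 2 Cebpb lost its call (0.0505, 0.0772 and 0.107), and Fos did without dDAVP replicate 2 (0.0725). Per1 lost it without any library but dDAVP replicate 3 (0.0513 to 0.13), and Elf3 without vehicle replicate 1 or 2 or dDAVP replicate 1 or 2 (0.0572 to 0.129). Lrrc7, Daam2, Vmn2r101, Olfr56, Cacna1e, Olfr1330 and Ntrk2 lost it without any of the same 4 libraries. Olfr398 and Cryzl2 lost it without 3 of them, all but vehicle replicate 2 and vehicle replicate 1 in turn (0.0514 to 0.123 for these 9 genes). Nr4a3 lost its call without any of the 6 libraries (0.0537 to 0.131).

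At 12 h, Aqp2 rose from 6.93 ± 1.45 to 136 ± 9.18 CPM (log2 4.31 ± 0.164, adjusted p = 3.78e-15). Complement C3 (chromosome 17, 57203970 to 57228136) rose from 23.4 ± 4.43 to 63.7 ± 7.72 CPM (1.45 ± 0.151, adjusted p = 4.09e-06). The mucin gene Muc4 went from 17.9 ± 2.81 to 42.9 ± 2.08 CPM (1.26 ± 0.13), and Aqp5, another water channel, from 22.2 ± 2.87 to 52.9 ± 5.69 CPM (1.26 ± 0.135). Aqp5 (chromosome 15, 99590782 to 99594829) lies close to Aqp2, and whether their rises are separate was not tested. B3gnt7 (2.05), Pde4b (2.01), Baiap2l2 (1.73), Arg2 (1.14), the sulfotransferase Sult1d1 (1.02) and Nipal1 (0.94) completed the largest rises, and no lower gene met the rule for naming. A total of 23 genes were called, 22 higher and 1 lower, and 88 (63 and 25) with the receptor share in the model, which included all 23. The receptor share spanned a wide range in vehicle at this time (SD 0.285%).

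No list passed camera at 12 h: 0 of 48, with 6 at an unadjusted p under 0.05, 2 by fry and 0 with the covariate. Nr4a1 had log2 0.79 (adjusted p = 0.0536; 0.00532 with the covariate) and Crem 0.62 (0.761; 0.0372 with the covariate). Per1, Fos, Sgk1, Creb1, Elf3, Cebpb, Aqp3, Aqp4, Avpr2 and the 3 sodium channel genes did not pass at 12 h in either model. The count without vehicle replicates 1, 2 and 3 was 13, 62 and 14, and without dDAVP replicates 1, 2 and 3 it was 14, 10 and 11. Arg2 kept its call only when vehicle replicate 2 was left out (0.0886 to 0.367 otherwise). Sult1d1 lost it without vehicle replicate 1 or dDAVP replicate 2 (0.105 and 0.0893), and Nipal1 without vehicle replicate 3 or dDAVP replicate 1 or 2 (0.253, 0.321 and 0.232).

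At 24 h, Aqp2 reached 224 ± 10.7 CPM in dDAVP against 5.49 ± 1.03 in vehicle (log2 5.34 ± 0.171, adjusted p = 6.17e-17). C3 was at 68.5 ± 4.6 against 22.1 ± 3.26 CPM (1.63 ± 0.152, adjusted p = 6.18e-07). Sult1d1 was at 24.2 ± 3.74 against 8.11 ± 1.43 CPM (1.58 ± 0.171), and the transglutaminase gene Tgm2 at 18.3 ± 1.73 against 7.93 ± 0.598 CPM (1.21 ± 0.13). Other large rises were those of B3gnt7 (2.02), Baiap2l2 (1.80), Pde4b (1.76), the alcohol dehydrogenase Adh1 (1.54) and Aqp5 (1.18). Rasl11a was the single lower gene called, at 7.9 ± 1.24 against 17.5 ± 2.18 CPM (-1.15 ± 0.193, adjusted p = 0.00669). A total of 25 genes were called, 24 of them higher, and 104 (75 higher, 29 lower) with the receptor share in the model, which included all 25. Receptor shares of the groups at 24 h, 0.226% and 0.201%, lay close together.

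At 24 h 3 of the 48 lists passed camera, against 0 with median-of-ratios scaling and 2 by fry. The principal cell markers (adjusted p = 0.00487) and the osmotic response list (0.00447) had 1 called member each, Aqp2 in both cases (1 higher and 0 lower adjusted over each list alone). Without Aqp2, a test added after seeing the data, these lists gave 0.882 and 0.662. With the covariate the principal cell list missed the threshold (0.0818) and the osmotic list kept its call (0.00787). The cAMP list (0.0491) had Pde4b and Akap12 called (4 higher and 0 lower adjusted over the list alone), with median -0.03 and mean 0.03, and gave 0.342 with the covariate. Nr4a1 rose (0.78, adjusted p = 0.0474), and Fos (0.53), Crem (0.34), Per1 (-0.08), Sgk1 (0.09), Creb1 (0.16), Elf3 (0.08), Cebpb (-1.07), Aqp3 (0.17), Aqp4 (0.22), Avpr2 (0.13), Scnn1a (-0.21), Scnn1b (0.26) and Scnn1g (-0.34) did not pass.

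Without vehicle replicate 1, 2 or 3 the count at 24 h was 15 each time, and without dDAVP replicate 3 it was 14. Calls were lost for Adh1 without vehicle replicate 1 or 3 or dDAVP replicate 2 or 3 (adjusted p 0.0519 to 0.138), for Rasl11a without vehicle replicate 1 or 2 or dDAVP replicate 1 or 3 (0.0649 to 0.109), and for Nr4a1 without any library but dDAVP replicate 2 (0.207 to 0.51).

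Calls at different times overlapped. Genes called in the same direction numbered 136 for 3 and 6 h (29.8 for independent lists), 18 for 3 and 12 h (0.103) and 20 for 3 and 24 h (0.112). They numbered 22 for 6 and 12 h (4.76), 24 for 6 and 24 h (5.18) and 19 for 12 and 24 h (0.0178), with 0 in opposite directions for any pair. With the receptor share in the model, 3 and 6 h shared 70 genes and 12 and 24 h shared 51. Across genes, which are not independent replicates, the log2 fold changes of 3 and 6 h had Pearson r = 0.52 and Spearman rho = 0.729 (0.241 and 0.316 with the covariate), and those of 12 and 24 h 0.0512 and 0.204 (0.00828 and 0.0802). Over genes of at least 5 CPM Pearson r was 0.756 for 3 and 6 h (0.288 with the covariate) and 0.479 for 12 and 24 h (0.411). It was 0.455 for 3 and 12 h (0.112) and 0.326 for 3 and 24 h (0.217). For 6 and 12 h it was 0.383 (-0.11), and for 6 and 24 h 0.273 (0.136). Higher at all 4 times were 16 genes, named here after their values were seen because the set is small: Add3, Akap12, Aqp2, Aqp5, Arg2, Arhgef3, B3gnt7, Baiap2l2, Cited1, Eya2, Inmt, Lypd3, Muc4, Nipal1, Pde4b and Sult1d1. With the covariate 33 genes were higher at all 4 times and 1, Rasl11a, was lower.

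**Figure D2:**
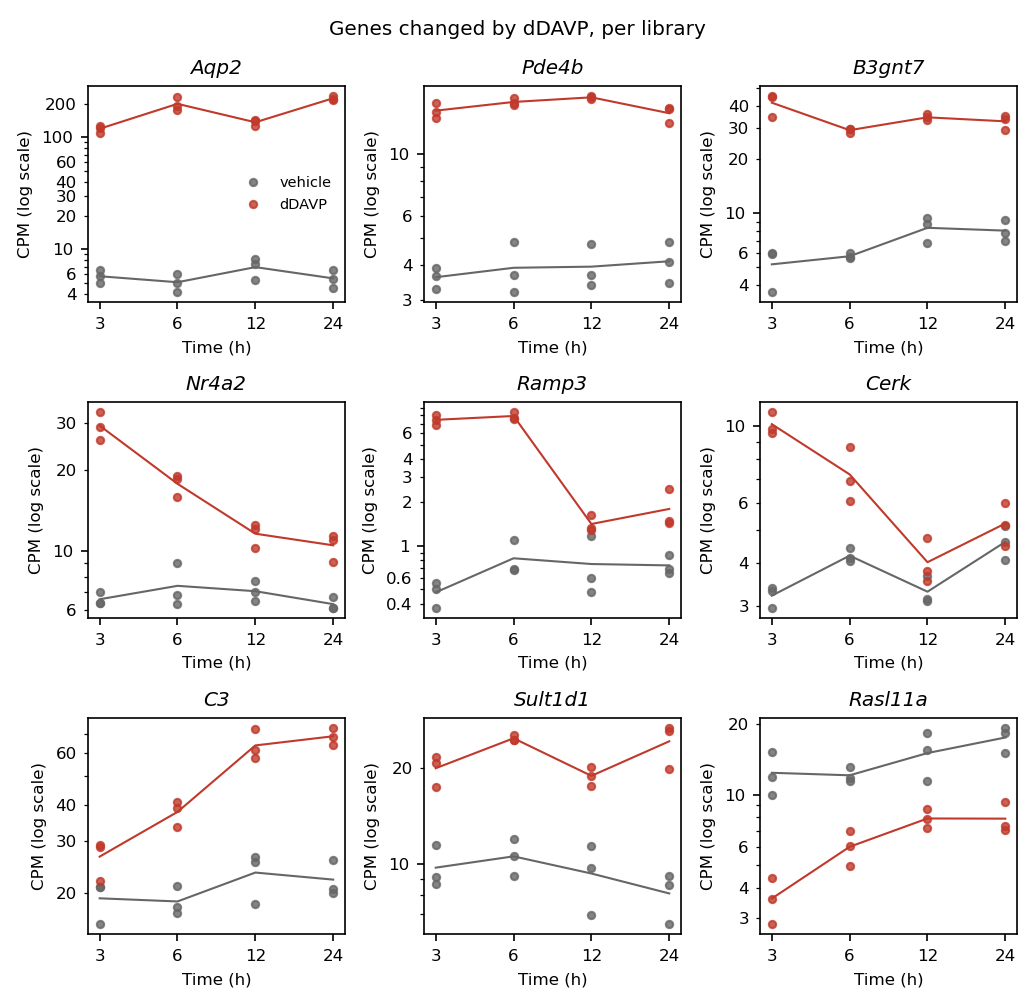
CPM (y axis, log scale, TMM library sizes) of 9 genes by time of treatment in hours (x axis), with 1 point per library and lines through the means of 3 libraries. Aqp2, Pde4b and B3gnt7 stay higher in dDAVP at all times, Nr4a2, Ramp3 and Cerk are farthest from vehicle at 3 or 6 h, C3 is at 68.5 CPM in dDAVP at 24 h, and Rasl11a is lower in dDAVP.

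Averaged over the 4 times, the genes with the smallest p were Aqp2 (log2 4.83 ± 0.084), B3gnt7 (2.35 ± 0.08), Pde4b (1.93 ± 0.082), Baiap2l2 (1.90 ± 0.09), Aqp5 (1.33 ± 0.068), and Muc4 (1.31 ± 0.065). They were followed by the retinoic acid-binding protein gene Crabp2 (1.13 ± 0.068), Akap12 (1.08 ± 0.065), Lypd3 (1.01 ± 0.054) and the adducin gene Add3 (0.97 ± 0.058). Their adjusted p ranged from 2.02e-23 for Aqp2 to 1.67e-11 for Add3, Akap12 and Crabp2. Every one passed with the receptor share in the model, from 4.81 for Aqp2 to 0.85 for Add3. A total of 9854 genes were called for the mean effect, 4970 higher and 4884 lower. The median shift was -0.20 over all tested genes and 0.14 over those of at least 5 CPM. Of the 9854, 6317 were genes of at least 5 CPM. A new fit after the 5 CPM filter called 3963 (1630 higher, 2333 lower; 3270 shared), and the fit with the covariate 364 (283 higher, 81 lower; 301 shared with the 9854).

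The cAMP list passed camera for the mean effect in both models (adjusted p = 0.00772, and 0.00152 with the covariate, in which 8 members were higher and 0 lower; 10 and 1 adjusted over the list alone). The CREB-associated list did too (0.0438 and 0.00299; 10 higher and 1 lower with the covariate, 13 and 2 adjusted over the list alone). The principal cell list (4 higher, 2 lower) and the osmotic list (5 higher, 1 lower; for each list the same counts adjusted over the list alone) gave 0.0406 and 0.0214, 0.0975 and 0.00152 with the covariate (1 higher, 3 lower, and 1 higher, 0 lower; 4 and 4, and 3 and 1, adjusted over the list alone), and 0.698 and 0.293 without Aqp2. With median-of-ratios scaling each of these 4 lists gave 0.337. The CREB-associated list, which does not hold Aqp2, gave 0.0876 when Aqp2 was taken out of the lists that do. Its unadjusted p is not changed by this, and only the adjustment over lists moved. Counts for the mean effect moved by more than 1.5 times when any of 17 of the 24 libraries was left out, from 1227 without vehicle replicate 3 of 24 h to 16748 without vehicle replicate 2 of 12 h.

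**Figure D3:**
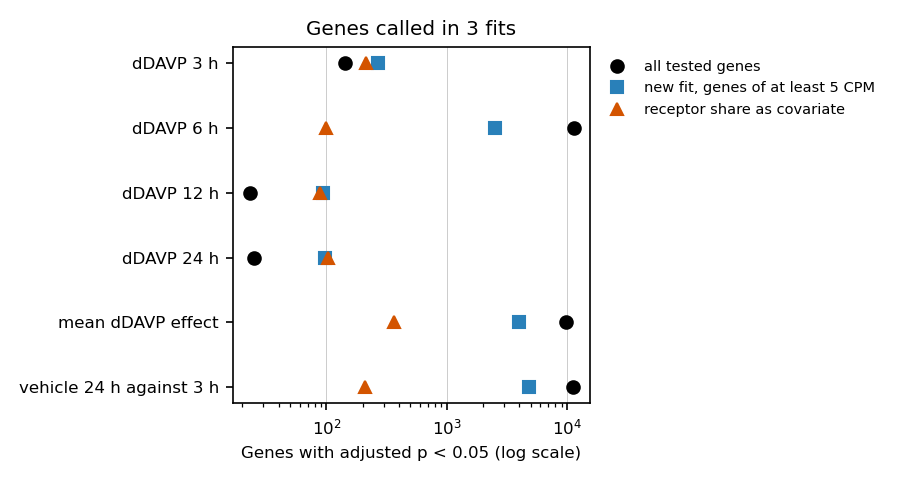
Genes with adjusted p under 0.05 (x axis, log scale) in 6 comparisons (y axis), for all tested genes, for a new fit to the genes of at least 5 CPM in a group, and for all tested genes with the log2 receptor share as a covariate. At 6 h the counts are 11320, 2500 and 100, and at 24 h they are 25, 97 and 104.

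Whether the dDAVP effect changed with time was tested directly. Nr4a2 was higher by log2 2.15 at 3 h, 1.26 at 6 h, 0.71 at 12 h and 0.73 at 24 h, and its effect at 24 h was below that at 3 h (difference -1.42 ± 0.208, adjusted p = 0.0115). Ramp3 went from 3.95 and 3.26 at 3 and 6 h to 0.93 and 1.28 at 12 and 24 h (-2.67 ± 0.438, adjusted p = 0.0224), and Cerk from 1.65 at 3 h to 0.18 at 24 h (-1.47 ± 0.256, adjusted p = 0.0348). The other genes with a smaller effect at 24 h were the von Willebrand domain gene Vwa2 (-1.10 ± 0.197), Dop1b (-0.89 ± 0.137) and the autophagy gene Tecpr1 (-0.76 ± 0.127). In all, 6 genes were called, 0 of them with a larger effect at 24 h. C3 had the opposite course, 0.47 at 3 h and 1.63 at 24 h (difference 1.15 ± 0.213, adjusted p = 0.0545; 0.00128 with the covariate).

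The test over all 4 times called 102 genes, 99 of them of at least 5 CPM. A new fit after the 5 CPM filter called 67 (35 shared), and the fit with the covariate 76 (47 shared). Its smallest p went to Tecpr1 and Ramp3 (each adjusted p = 0.00362), Nr4a2 (0.00486), and Vwa2 and Dop1b (each 0.00599). Next came the sterol acyltransferase Soat1 and Fbrsl1 (each 0.0208), Pwwp2a and the phosphatase subunit gene Ppp2r2d (each 0.023) and Adgra3 (0.0296). Mean CPM of Fbrsl1, Pwwp2a, Ppp2r2d and Adgra3 was higher in dDAVP than in vehicle at 3 and 6 h and lower at 12 and 24 h. Libraries of a group could differ widely, as for Adgra3 in vehicle at 3 h (15.8, 32.6 and 45.3 CPM). In the same libraries Pwwp2a was at 13.1, 23.2 and 34.2 CPM, Ppp2r2d at 11.1, 20.8 and 24.3, and Fbrsl1 at 11.4, 13 and 17.4. In dDAVP at 24 h Adgra3 was at 37.5, 23.5 and 16.2, Pwwp2a at 28.3, 20.2 and 16.5, Ppp2r2d at 23.1, 15.6 and 13.2, and Fbrsl1 at 13.8, 14.3 and 10.7. These genes thus varied together between replicates, and their changes of direction need not be separate effects of dDAVP. With the covariate 64 genes differed between 24 and 3 h (15 with a larger and 49 with a smaller effect at 24 h), including the 6. Without dDAVP replicate 3 of 3 h Tecpr1 and Nr4a2 lost this call (each 0.0576), Ramp3 kept it throughout, and the other 7 lost it in 9 (Dop1b) to 17 (Adgra3) of 24 omissions. Each of the 6 genes that differed between 24 and 3 h lost that call in 7 (Nr4a2) to 11 (Tecpr1, Cerk and Vwa2) of 12 omissions. Leaving out a library gave 0 to 8 genes for 24 against 3 h, a move of more than 1.5 times for every library of the 12 but dDAVP replicate 1 of 3 h. Over all times it gave 1 (without dDAVP replicate 3 of 3 h) to 249 (without vehicle replicate 1 of 3 h), with 21 of 24 libraries moving the count by more than 1.5 times.

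In vehicle alone, single genes for glycolytic enzymes and HIF targets were higher at 24 h than at 3 h. The glycolytic enzyme gene Pfkl (chromosome 10, 77986947 to 78010083) was at 679 ± 49.5 against 223 ± 33.1 CPM (log2 1.61 ± 0.156, adjusted p = 2.77e-06), Gpi1 at 465 ± 36.7 against 189 ± 25.4 CPM (1.30 ± 0.139) and Aldoc at 48.1 ± 2.35 against 19.3 ± 2.64 CPM (1.32 ± 0.151). Pdk1, which restrains pyruvate dehydrogenase (chromosome 2, 71873224 to 71903858), was at 165 ± 12 against 54.7 ± 6.85 CPM (1.60 ± 0.149), and the mitophagy gene Bnip3 at 153 ± 19.2 against 30 ± 4.59 CPM (2.35 ± 0.245). Fam162a (1.65), the ammonia transporter Rhcg (1.15), Selenom (1.29), Tspyl4 (0.93) and the endocytic receptor Lrp1 (0.90) made up the 10 smallest p. All 10 passed with the receptor share in the model, where Pfkl was at 1.24, Pdk1 at 1.25, Bnip3 at 1.84 and Fam162a at 1.14.

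**Figure D4:**
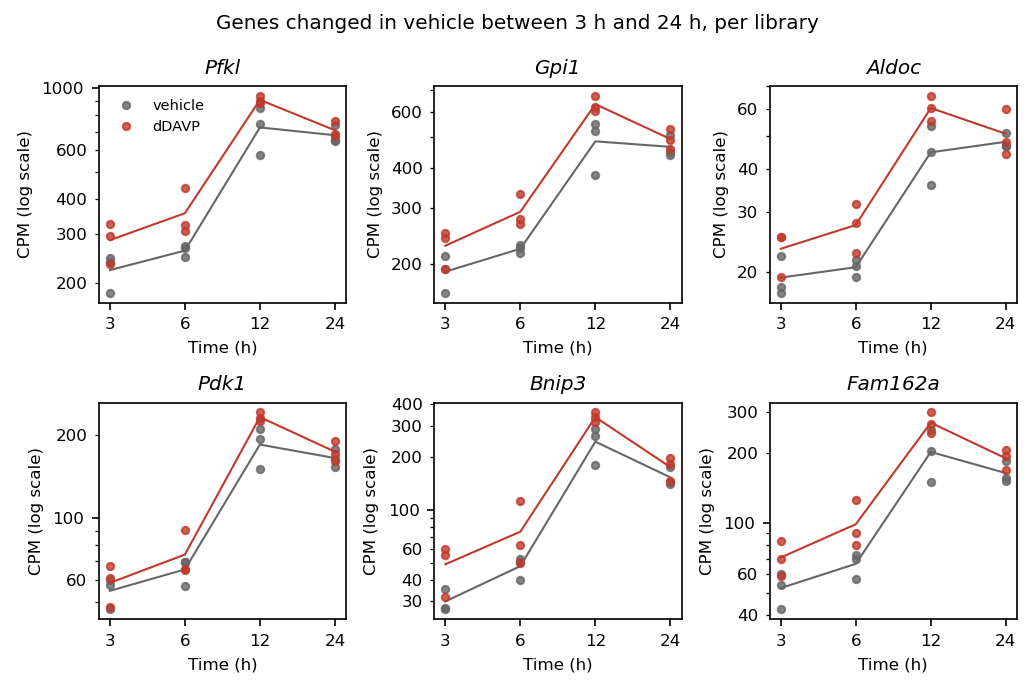
CPM (y axis, log scale, TMM library sizes) of 6 genes of glycolysis and the low-oxygen response by time of treatment in hours (x axis), with 1 point per library and lines through the means of 3 libraries in vehicle and dDAVP. In vehicle Pfkl goes from 223 CPM at 3 h to 679 CPM at 24 h.

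Of 19 glycolysis genes, 14 rose and 0 fell in vehicle (14 and 1 adjusted over the list alone), and 12 and 0 with the covariate (13 and 1), with Pfkp at 1.21 beside the genes above. The list passed camera with the covariate (adjusted p = 0.017, median 0.43) and not without it (0.176, median 0.85). Of 27 hypoxia and HIF target genes, 16 rose and 0 fell (16 and 0 adjusted over the list alone; 7 and 0 with the covariate, 9 and 1 adjusted over the list alone), with Aldoa at 1.40 and Pgk1 at 1.14, and camera gave 0.363 and 0.129. Of 19 circadian clock genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone; 5 and 0 with the covariate, 6 and 1 adjusted over the list alone). Per2 (1.08), Tef (0.95) and Cry2 (0.70) were among them, and camera gave 0.363 and 0.129. List tests in vehicle and on the mean effect were added after seeing the data. Without the covariate 0 of 48 lists passed camera in vehicle, against 5 at an unadjusted p under 0.05 and 34 by fry. Over all tested genes 5460 were called higher without the covariate, 97.82% of them of at least 5 CPM. Counts of called members alone therefore do not set a list apart.

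Calls in vehicle came to 11312 genes, 5460 higher and 5852 lower at 24 h, and 6905 of them were genes of at least 5 CPM. A new fit after the 5 CPM filter called 4867 (2190 higher, 2677 lower; 4018 shared), and the fit with the covariate 208 (161 higher, 47 lower; 168 shared). The receptor share was 0.629% at 3 h and 0.226% at 24 h, and the median log2 fold change was -0.44 over all tested genes and 0.30 over those of at least 5 CPM. The count was 443 without vehicle replicate 1 of 3 h, 6052 without replicate 2 of 3 h, and 1534 and 2243 without replicates 1 and 2 of 24 h.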

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

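The tests with the receptor share as a covariate, those of the hypoxia and glycolysis medians in vehicle as a product of the receptor share, and that of glycolysis in dDAVP libraries were chosen after seeing the result; the other tests here were written before theirs were seen.

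Effects of dDAVP that differed between times were singled out because a test of the difference itself passed: 102 genes over the 4 times by edgeR's quasi-likelihood test with BH adjustment, and 6 between 24 h and 3 h. The difference of log2 effects, 24 h minus 3 h, was -1.422 for Nr4a2, -0.886 for Dop1b, -2.669 for Ramp3, -0.761 for Tecpr1, -1.469 for Cerk and -1.105 for Vwa2. With the covariate the same differences were -1.35, -0.86, -2.49, -0.76, -1.46 and -0.97, each with an adjusted p from 0.000579 to 0.00128. With median-of-ratios scaling the counts fell to 1 over the 4 times and 0 between 24 h and 3 h. A fit of only the libraries compared called 1 gene between 24 h and 3 h. Groups of 3 libraries were not tested for single outlying samples.

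The 11320 genes called at 6 h were weighed against the receptor share, depth and a dDAVP response. With the receptor share in the model 100 were called, 85 of them among the 11320, which fits a difference in reads from silent genes between the groups. With every library thinned to 17.25 M counts 6029 were called (1417 higher, 4612 lower), which leaves sequencing depth undecided. Across 11181 called genes the fold change at 6 h followed the slope on the receptor share in the 18 libraries of the other times (r = -0.889, Spearman rho = -0.84). By the rule set beforehand this speaks against a dDAVP response of the called genes as a set. Of the higher genes 98.6% reached 5 CPM in a group, and of the lower genes 27.75%. That contrast alone could give such a correlation, which was not computed within higher or lower genes. It therefore cannot exclude a response to dDAVP. The 85 genes called in both models differed between dDAVP and vehicle beyond the share as modelled. The covariate may also absorb a response to dDAVP, since the share itself differed between these groups.

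The 11312 genes called in vehicle between 24 h and 3 h were weighed against the receptor share and a change over the hours of culture. With the share in the model 208 were called, 168 of them among the 11312, which fits a difference in reads from silent genes. The covariate may also absorb a change over the hours of culture, since the shares of these groups did not overlap. They were 0.3908% to 0.9013% at 3 h and 0.1809% to 0.3007% at 24 h. The median of the glycolysis list was still 0.4339 in vehicle (camera adjusted p = 0.017), against the share as its whole source. Without the covariate the vehicle median was larger and the list did not pass camera. In dDAVP libraries the median with the covariate was 0.5158 (0.0233), which fits a change over culture in both arms. The median of the hypoxia list was 0.1755 in vehicle (0.129) and 0.03347 in dDAVP libraries (0.635), so that for this list the receptor share and a change over culture cannot be told apart.

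Counts in the silent receptor genes were weighed against genomic DNA and against a few receptor genes taking most of the reads. Counts rose with transcript length across receptor genes (Spearman rho = 0.764), which fits reads from genomic DNA, although other even sources of reads could give the same relation. The 10 receptor genes with the most counts held 17.07% of them, which speaks against a few genes as the source. No biological explanation was tested for this pattern.

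Other splits of the libraries were compared with the real one. With 10 splits of 3 against 3 libraries, splits are too few for a share under 0.05. Of 10 splits at 3 h, 2, the real one included, gave at least the 144 calls of the real one. The other gave 5822, with vehicle replicates 1 and 2 and dDAVP replicate 1 against the rest. This points to a structure of the samples other than treatment. That split parts the 3 h libraries by receptor share (0.9013%, 0.5958% and 0.5087% against 0.3908%, 0.2746% and 0.3374%), a relation seen after the splits were run and not tested. At 6, 12 and 24 h, 1 split each, the real one, gave as many as 11320, 23 and 25, with 0, 17 and 1 as the highest other. The 17 came from vehicle replicates 1 and 3 with dDAVP replicate 1, again the 3 highest shares of that time (0.7453%, 0.5076% and 0.3807%). In vehicle 1 split, the real one, gave as many as 11312, with 1 as the highest other. The real splits at 6 h and in vehicle also part the libraries by receptor share. At 6 h the shares were 0.5529%, 0.5811% and 0.4433% in vehicle against 0.1769%, 0.1348% and 0.2763% in dDAVP. In vehicle they were 0.3908% to 0.9013% at 3 h against 0.1809% to 0.3007% at 24 h. The counts of these real splits therefore cannot tell treatment or time from the share. Of 100 splits, the real one included, 3 gave at least 102 for the dependence on time (highest other 14004). For 24 h against 3 h 1 gave at least 6 (highest other 4), and for the mean effect 2 gave at least 9854 (highest other 10408). The high values of other splits again point to a structure of the samples.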

How the results depend on the processing

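Fits with the receptor share as a covariate, alone or with the 5 CPM filter, fits without the 2 libraries of highest share, list tests without Aqp2, and all list tests on the mean effect and in vehicle were chosen after seeing the data; other alternatives were planned. The cause of a change was not tested, except that a threshold of 0.01 lowers a count by construction. The 5 CPM filter led to a new fit with its own scaling, so its counts are not the calls among those genes. All counts are of edgeR's quasi-likelihood test with BH unless another tool is named.

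At 3 h (144) the count was 70 with RLE, 267 at 5 CPM, 135 by limma on TPM plus 1 (58 higher, 77 lower) and 93 plus 0.1 (52, 41), 68 with only the libraries compared, and 90 at 0.01. It was 277 with covariate and filter, and 63 (without dDAVP replicate 3) to 206 (without vehicle replicate 3) leaving out a library. At 6 h (11320) it was 4932 with no filter, 2500 at 5 CPM, 6525 by limma on TPM plus 1 (79 higher, 6446 lower), and 201 at 0.01. It was 100 with the covariate, 159 with covariate and filter, and 84 to 9333 leaving out a library. At 12 h (23) it was 10 with RLE, 93 at 5 CPM, 7 with only the libraries compared, and 13 at 0.01. It was 88 with the covariate, 196 with covariate and filter, 15 without the 2 libraries, and 10 to 62 leaving out a library. At 24 h (25) it was 15 with RLE, 97 at 5 CPM, 45 with only the libraries compared, and 16 at 0.01. It was 104 with the covariate, 177 with covariate and filter, 41 without the 2 libraries, and 14 to 19 leaving out a library.

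Dependence on time (102) gave 1 with RLE, 155 by DESeq2, 207 with no filter, 67 at 5 CPM, 5 by limma on TPM plus 1 and 5 plus 0.1, and 5 at 0.01. It gave 407 without the 2 libraries, and 1 to 249 leaving out a library. For 24 h against 3 h (6) it was 0 with RLE (8 by DESeq2; 1609 genes had unadjusted p under 0.05 in the planned fit), 3 with no filter, 36 at 5 CPM, 7 by limma on TPM plus 1 (4 larger, 3 smaller) and 6 plus 0.1 (3, 3), 1 with only the libraries compared, and 0 at 0.01. It was 64 with the covariate, 75 with covariate and filter, and 0 to 8 leaving out a library. The mean effect (9854) gave 6300 with RLE, 4930 with no filter, 3963 at 5 CPM, and 391 at 0.01. It gave 364 with the covariate, 447 with covariate and filter, 679 without the 2 libraries, and 1227 to 16748 leaving out a library. Vehicle (11312) gave 4867 at 5 CPM, and 1974 at 0.01. It gave 208 with the covariate, 679 with covariate and filter, 2851 without the 2 libraries, and 443 to 15327 leaving out a library. On TPM plus 0.1 most calls were lower at 6 h (102 higher, 10488 lower), for the mean effect (173, 10565) and in vehicle (282, 10688). Gm24245, noted after its values were seen, held 37.44% to 51.66% of a TPM column, and 43.51%, 43.19% and 46.85% in vehicle against 48.97%, 51.66% and 51.43% in dDAVP at 6 h. No fit without it was run.

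Lists called at 3 h (1) numbered 37 with the preset correlation, 7 by fry, 0 with RLE and 2 with the covariate. At 6 h (0) they numbered 38, 44 by fry, 2 with the covariate and 3 with covariate and filter. At 12 h (0) they were 28 and 2 by fry, and at 24 h (3) 19, 0 with RLE, 0 without Aqp2, and 1 with the covariate, with or without the filter. The cAMP list does not hold Aqp2, so its call at 24 h was lost without Aqp2 only through the adjustment over lists. Shared calls with RLE and with the covariate were 65 and 70 for 3 and 6 h (136), 8 and 50 for 3 and 12 h (18), and 10 and 45 for 3 and 24 h (20). They were 9 and 47 for 6 and 12 h (22), 14 and 45 for 6 and 24 h (24), and 9 and 51 for 12 and 24 h (19).

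The replicate block was run although replicate numbers do not pair the libraries: deviations from the group mean correlated from -0.490 to 0.699 between libraries of the same number, and 8 of 24 libraries correlated best with their own number. With the replicate block 37 genes were called at 12 h, 57 for the dependence on time, 1 list at 12 h, and 30 and 35 genes were shared between 3 and 12 h and between 6 and 12 h.

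There were 177 pairs of a named gene and a comparison, 119 past the threshold. Direction and side of the threshold were kept in 151 with RLE, 170 by DESeq2 and 144 with the covariate. They were kept in 128 by limma on TPM plus 1, in 126 plus 0.1, and in 129 of 166 with covariate and filter. Leaving out a library, they were kept in 132. Each pair was judged there only by the omission with the largest p, so calls gained in other omissions were not counted. With the alternative past the threshold, directions turned for Avpr2 at 6 h on TPM (-0.289 plus 1, -0.308 plus 0.1) and for Scnn1a at 6 h on TPM (-0.358, -0.386) and with covariate and filter (-0.389). Directions also turned with neither value past it, 54 times over all pairs and alternatives, among them Creb1, Avpr2 and Scnn1a at 6 h with the covariate. In simulated data, which lack the common variation in receptor share, small changes were missed: at 6 h 46.3% of 1.5-fold changes were recovered.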

Other observations

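Avpr2, the V2 receptor, was higher in vehicle at 24 h than at 3 h (log2 0.83, adjusted p = 0.000591 by edgeR's quasi-likelihood test with BH; 0.48 and 0.0154 with the covariate). This contrast for Avpr2 was chosen after its values were seen. Group means of Aqp2 in vehicle stayed between 5.07 and 6.93 CPM at all 4 times, while those in dDAVP were 119 to 224 CPM.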
